A study of Arabidopsis thaliana with 25 samples.

How the data were processed

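The deposited table holds 1 value per probe set and array for 25 Affymetrix ATH1 arrays of Arabidopsis Col-0 seedlings, 13 from roots and 12 from shoots, of WT, mpk6 and MPK6ox in normoxia and hypoxia. Its values are log2 expression values that the authors made with RMA, per the submitters' processing notes, which give no version. RNA was labelled with a 2-cycle biotin protocol, per the labels' protocols. The values run from 3.60 to 15.1, and the sorted values of different arrays lie within 0.534 of each other, as after a quantile-type normalization, although the notes do not say whether all 25 arrays were normalized together. They were used as deposited, with no further scaling and no filter on dim probe sets. Signal over background was not assessed, so a fold is a ratio of the deposited values. Arrays have no depth, and their number per group, 2 or 3, limits the precision.

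Samples were grouped by genotype, organ and treatment as the labels give them. Of the 22810 probe sets, 64 control probe sets (AFFX) were left out and 22746 tested. Through the probe table of the array, 13513 of these carried 1 gene, 503 carried several, and the genes of the other 8730 were not used here. Of the first, 13436 were matched to a gene of the reference annotation (TAIR10.1) by gene ID, and 77 kept their symbol, which made 13355 different genes. MPK6 and the list members beyond those counted below were not analysed here. The signal of the 3' end minus that of the 5' end of the control transcripts was read from the AFFX probe sets of each array.

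Tests used limma 3.58.1 in R 4.3.3 with a model of 12 group means, contrasts and empirical Bayes moderation (13 residual and 3.41 prior degrees of freedom). The 21 comparisons were the hypoxia effect in each genotype and organ (6), each line against WT within organ and treatment (8), the difference of the hypoxia effect between each line and WT in each organ (4), the difference between WT roots and WT shoots, and each line against WT averaged over organs and treatments (2). P-values were adjusted by Benjamini and Hochberg within a comparison over all tested probe sets, and a probe set was called at an adjusted p under 0.05. Single-gene errors are standard errors of the fitted change, and group values are means with SD. Tables and figures were made in Python 3.11.15 with matplotlib 3.10.9.

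The comparisons, the alternatives, the gene lists and the rule for named genes were set before the data were examined. By that rule the text could name MPK6, the 10 largest rises and 10 largest falls in the hypoxia effects of WT roots and of WT shoots, and up to 5 each way in every other comparison, all from called probe sets that carry exactly 1 gene and whose arrays do not overlap between the groups (the overlap condition was dropped for differences of effects), and members of the lists. A list member was read from the probe set with its highest mean over the 25 arrays. No named gene had a further probe set that was called the opposite way. As exceptions MPK6 was not analysed here, and genes named in the other observations outside the rule were chosen after their values were seen.

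The 18 lists hold 342 different genes, of which 72 were measured. Measured and total members were 4 of 18 for fermentation, glycolysis and sucrose breakdown, 24 of 42 for other low-oxygen response genes, 6 of 24 for heat shock, 9 of 18 for mitochondrial dysfunction, 3 of 18 for defence and stress genes linked to MPK3 and MPK6, 3 of 12 for touch, 3 of 17 for abscisic acid, 3 of 17 for salicylic acid and pathogen defence, 6 of 18 for cell wall loosening, 6 of 30 for photosynthesis as a marker of shoot tissue, and 3 of 21 for root tissue markers. Of the peroxide (15), ethylene (22), starvation (19), cell division (16) and clock (13) lists 1 gene each was measured, and of the MAP kinase (18) and jasmonate (17) lists 0, so the last pair gave no result. CML38 stands in the low-oxygen and touch lists, WRKY53 in the MPK3 and MPK6 and salicylic acid lists, and STZ in the peroxide and the MPK3 and MPK6 lists. The 11 lists with at least 3 measured genes were tested with limma's camera (preset correlation 0.01), adjusted over the lists within each of 13 comparisons, with camera at an estimated correlation and fry beside it. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Intervals of list means are 95% intervals from a fit of the mean value of the list per array.

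Alternatives were the replicate numbers as a block, roots and shoots fitted separately, the dimmest 5687 probe sets left out, quantile normalization over all 25 arrays, arrays centred on their medians, empirical Bayes with trend and robust settings, array weights, and each array left out in turn. After the data were seen, 3 were added: shoot-enriched probe sets left out, the mean of the 6 photosynthesis genes of the root arrays as a covariate, and seed genes left out. The titles number the biological replicates. Deviations of arrays from their group means were correlated between same-numbered arrays of the groups compared. For each averaged genotype comparison there are 8 such pairs, with correlations from 0.351 to 0.653 over both. There the numbers were taken to pair the samples, and the blocked count stands beside the result. Where both groups hold 2 arrays, the 2 pairs give the same correlation, so the 8 are not separate values. In the hypoxia comparisons the correlation was 0.0294 in WT roots and from 0.232 to 0.588 in the others. Because of the lowest value the numbers were not taken to pair the samples there. Blocked counts of hypoxia comparisons that moved by over 1.5 times are given with the processing. The comparisons of a line with WT within an organ and treatment use 2 of these pairs each, and their blocked count is given where it moved by over 1.5 times.

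The steps were tested on simulated data with each probe set's mean over all arrays and its moderated spread. There were 5 simulations of 22746 probe sets with 200 changed. Noise was drawn independently for each array, whereas same-numbered arrays deviated together in the data. The rates that follow thus need not hold for the data. For the hypoxia effect in WT roots 13.6%, 67.2%, 98.8% and 100% of changes of 0.5, 1, 2 and 4 log2 were recovered, and 6.55% of the calls were false. For the difference of the hypoxia effect between mpk6 and WT roots it was 1.60%, 40.0%, 92.0% and 99.2%, with 5.67% false, and for mpk6 against WT averaged over organs and treatments 73.6%, 100%, 100% and 100%, with 4.89% false. Correlations and overlaps between the averaged comparisons, which share the WT arrays, were set beside 20 simulations. In these every array, WT included, was simulated as unchanged, without correlation between arrays.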

Results

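Transcript levels were measured with 25 Affymetrix ATH1 arrays in roots and shoots of 10-day-old Arabidopsis Col-0 seedlings of 3 genotypes: the wild type (WT), mpk6, a T-DNA insertion knockout of the MAP kinase gene MPK6, and MPK6ox, in which a constitutive promoter drives MPK6. Whole seedlings were kept in an airtight chamber flooded with 99.998% argon (hypoxia) or in an open box (normoxia) and were dissected into root and shoot afterwards. The protocol gives 2 h for both treatments, whereas the source names of the hypoxia samples give 9 h, so the length of the hypoxia treatment is uncertain. The 12 groups of genotype, organ and treatment held 2 arrays each, except MPK6ox root hypoxia with 3. Median log2 values per array ran from 6.87 to 7.07, and arrays of the same group correlated at 0.982 or higher. MPK6 itself was not analysed here, so the genotype labels were not checked against the transcript of the targeted gene. Signal over background was not assessed, so a fold is a ratio of the array values. The number of arrays limits the precision, and every p-value measures only the spread between these samples.

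Hypoxia raised a limited set of transcripts in WT roots by very large factors. AT5G10040 went from 4.97 ± 0.07 in normoxia to 13.24 ± 0.27 in hypoxia (log2, SD, n = 2 and 2), a 310-fold rise of 8.28 ± 0.25 (SE, limma adjusted p = 9.49e-13). AT4G10270, a member of a wound-responsive protein family, rose 234-fold, AT4G33560 95.5-fold, and AT3G10040, which encodes a trihelix transcription factor, 75.2-fold. CML38, a calmodulin-like calcium sensor, rose 50.0-fold, by 5.64 ± 0.16 (adjusted p = 6.97e-13). The 10 largest rises ended with AT5G44730 at 26.8-fold, and all 10 belonged to the list of low-oxygen response genes fixed beforehand. The largest falls were smaller, with log2 changes between -2.96 and -2.23. EXPA18, a root-hair expansin, fell 5.63-fold (-2.49 ± 0.37), AT5G01210, of an acyltransferase family, 5.16-fold (-2.37 ± 0.36), AT4G00910, of a malate transporter family, 5.14-fold (-2.36 ± 0.24), and AT1G48690, of the GH3 family, 4.69-fold (-2.23 ± 0.18, adjusted p = 4.33e-07). AT1G12320 and AT1G49470 fell by 2.58 and 2.26. AT3G01260 (-2.96, adjusted p = 0.00518), the peroxidase gene AT1G34510 (-2.72, 0.0383), AT2G23270 (-2.47, 0.0156) and the EF-hand gene AT5G39670 (-2.27, 0.00772) also passed. Without WT root normoxia replicate 1, the adjusted p was 0.07 for AT3G01260, 0.233 for AT1G34510 and 0.0575 for AT2G23270. Without normoxia replicate 2 it was 0.0908 for AT1G34510, 0.102 for AT2G23270 and 0.0777 for AT5G39670. Without hypoxia replicate 1 it was 0.203 for AT2G23270 and 0.0874 for AT5G39670, without hypoxia replicate 2 it was 0.0986 for AT3G01260 and 0.369 for AT1G34510, and without MPK6ox shoot normoxia replicate 1 or 2 it was 0.0505 for AT1G34510.

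By limma, 1479 of 22746 probe sets changed with hypoxia in WT roots, 581 upward and 898 downward, and 386 of the rises and 345 of the falls were at least 2-fold. With each array centred on its median, 694 rose and 631 fell, so the rising share was 39.3% with the values as deposited and 52.4% after centring. The count was 612 without WT root normoxia replicate 1, 921 without hypoxia replicate 1 and 683 without hypoxia replicate 2. It was 852 when roots and shoots were fitted separately, which leaves each change as it was and alters its error, and there the adjusted p was 0.0547 for AT3G01260, 0.147 for AT1G34510, 0.0889 for AT2G23270 and 0.0636 for AT5G39670.

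The low-oxygen list, most of which are genes named for their induction by hypoxia, rose almost as a whole in WT roots: 22 of its 24 measured members rose, and 23 did when adjusted over the list alone. The list mean rose by 4.04 (95% interval 3.80 to 4.29), and limma's camera call held with an estimated correlation (adjusted p = 1.13e-06). Of the 4 measured genes of fermentation and sugar breakdown, 2 rose, also when adjusted over the list alone: PDC2, a pyruvate decarboxylase of ethanol fermentation, 14.0-fold (3.81 ± 0.64, adjusted p = 0.00138), and AT4G17260, a lactate dehydrogenase, 9.33-fold (3.22 ± 0.24, adjusted p = 1.81e-07). GAPC2 and PPDK, at 0.46 and 0.37, did not pass, and the list held with an estimated correlation (adjusted p = 0.00359). Among the 3 measured defence and stress genes linked to MPK3 and MPK6, the transcription factor gene WRKY22 rose 16.1-fold (4.01 ± 0.49, adjusted p = 5.48e-05), WRKY53 fell (-1.43, adjusted p = 0.0216) and STZ did neither (0.29), with the same counts adjusted over the list alone. The list mean was 0.96 (95% interval 0.15 to 1.76), and the list did not differ from other genes by camera (adjusted p = 0.47). Of the 3 touch genes, CML38 rose, also adjusted over the list alone, and its call carried the list's (camera adjusted p = 0.00808), which was lost with an estimated correlation (adjusted p = 0.0906). The touch list's mean was 1.83 and its median -0.01.

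Root marker genes fell in WT roots. Of the 3 root tissue markers, EXPA7 (-1.86, adjusted p = 3.14e-05) and EXPA18 fell and PYK10, a beta-glucosidase, did not pass (-0.44, adjusted p = 0.11), while all 3 fell when adjusted over the list alone. The list's shift held with an estimated correlation (adjusted p = 0.0192). Of 6 cell wall loosening genes, EXPB1 fell (-0.59, adjusted p = 0.0342), and 2 fell when adjusted over the list alone. That list's mean was -0.40 (95% interval -0.63 to -0.17), and fry called it lower (adjusted p = 0.0275), while camera did not call it relative to other genes (adjusted p = 0.19). In the same samples the photosynthesis genes, which serve as markers of shoot tissue, rose: PSBW (2.43, adjusted p = 0.00511), PRK (2.03, 0.0157), RCA (1.86, 0.0192) and PSAN (1.73, 0.0256) passed, and all 6 measured ones did when adjusted over the list alone. Their camera call (adjusted p = 5.7e-07) was lost with an estimated correlation (adjusted p = 0.0906). When the mean of these 6 genes in the root arrays was added to the model, a choice made after the data were seen, 521 probe sets changed with hypoxia in WT roots. Calls were then lost by AT1G34510, from -2.72 ± 0.75 (SE) to -0.08 ± 0.67 (adjusted p = 0.995), AT3G01260, from -2.96 ± 0.59 to -1.16 ± 0.63 (0.58), and EXPA18, from -2.49 ± 0.37 to -1.70 ± 0.48 (0.092), whose changes became smaller. AT5G39670 lost its call with a wider error and a change about as large, from -2.27 ± 0.48 to -2.24 ± 0.72 (0.161). The mean of the 6 genes itself rose with hypoxia, from 7.41 to 9.20 in WT roots. A model with it thus also takes up part of the hypoxia effect, and the lost calls do not show that shoot RNA made these falls.

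In WT shoots the same kind of genes rose. AT4G10270 rose 149-fold (7.22 ± 0.20, n = 2 and 2, limma adjusted p = 1.25e-12), AT5G10040 105-fold, AT3G10040 92.4-fold, AT5G66985 81.3-fold and CML38 38.8-fold, from 7.14 to 12.41. The falls were small: AT5G62280 went from 10.06 to 8.12 (-1.93 ± 0.25, adjusted p = 0.00022), AT5G58900 fell by 1.85 and AT5G57760 by 1.78, and AT3G50340 also fell (adjusted p = 0.00021). In total 214 probe sets rose and 99 fell, 169 and 50 of them at least 2-fold. A replicate block made this total over 1.5 times as high. The remaining falls among the 10 largest, AT1G23030 (-1.69), the expansin EXPA16 (-1.51), AT4G35720 (-1.47), AT5G12050 (-1.40), the GDSL lipase gene AT5G55050 (-1.31) and AT2G47440 (-1.30), had adjusted p between 0.0108 and 0.0316. Each depended on single arrays. Without WT shoot normoxia replicate 1 the adjusted p was 0.158 for AT1G23030, 0.14 for EXPA16, 0.089 for AT4G35720, 0.19 for AT5G12050 and 0.163 for AT5G55050. Without normoxia replicate 2 the values were 0.0848, 0.0708, 0.277, 0.188 and 0.168 for the same genes and 0.154 for AT2G47440. Without hypoxia replicate 1 they were 0.119 for EXPA16, 0.284 for AT4G35720 and 0.204 for AT5G55050, and without hypoxia replicate 2 they were 0.329 for AT1G23030, 0.515 for AT5G12050, 0.0521 for AT5G55050 and 0.254 for AT2G47440. With shoots fitted alone the adjusted p was 0.118 for AT1G23030, 0.0941 for EXPA16, 0.2 for AT4G35720, 0.111 for AT5G55050 and 0.0879 for AT2G47440. The total of 313 probe sets was 144 and 160 without normoxia replicates 1 and 2 and 127 without hypoxia replicate 2.

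Of the 24 low-oxygen genes 21 rose in WT shoots, 23 adjusted over the list alone, and the list mean rose by 3.65 (95% interval 3.41 to 3.89, adjusted p = 7.57e-08 with an estimated correlation). PDC2 rose (2.93, adjusted p = 0.0306), as did AT4G17260 (1.29, adjusted p = 0.0106), which made 2 of 4 fermentation genes, also adjusted over the list alone (adjusted p = 0.00278 with an estimated correlation). The touch list rose through CML38 alone, also adjusted over the list alone (adjusted p = 0.00278 with an estimated correlation). The MPK3 and MPK6 list had 0 of 3 genes past limma's threshold over all probe sets in WT shoots, with WRKY22 at 1.69 (adjusted p = 0.135) and STZ at 1.53 (adjusted p = 0.26). Of its genes 2 had an unadjusted p under 0.05, and both rose when adjusted over the list alone. The list's camera call (adjusted p = 0.00421) was lost with an estimated correlation (adjusted p = 0.0676). Heat shock genes had a mean of 0.70 with 0 of 6 past the threshold, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and their camera call (adjusted p = 0.0248) was lost with an estimated correlation (adjusted p = 0.481). The salicylic acid and pathogen defence list had 0 of 3 past the threshold, and its glutaredoxin gene GRX480 (1.17) was the 1 gene to pass when adjusted over the list alone. Its camera call (adjusted p = 0.0307) was lost with an estimated correlation (adjusted p = 0.12). The photosynthesis genes had a mean change of 0.00 in WT shoots, with 0 of 6 past the threshold, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

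**Figure D1:**
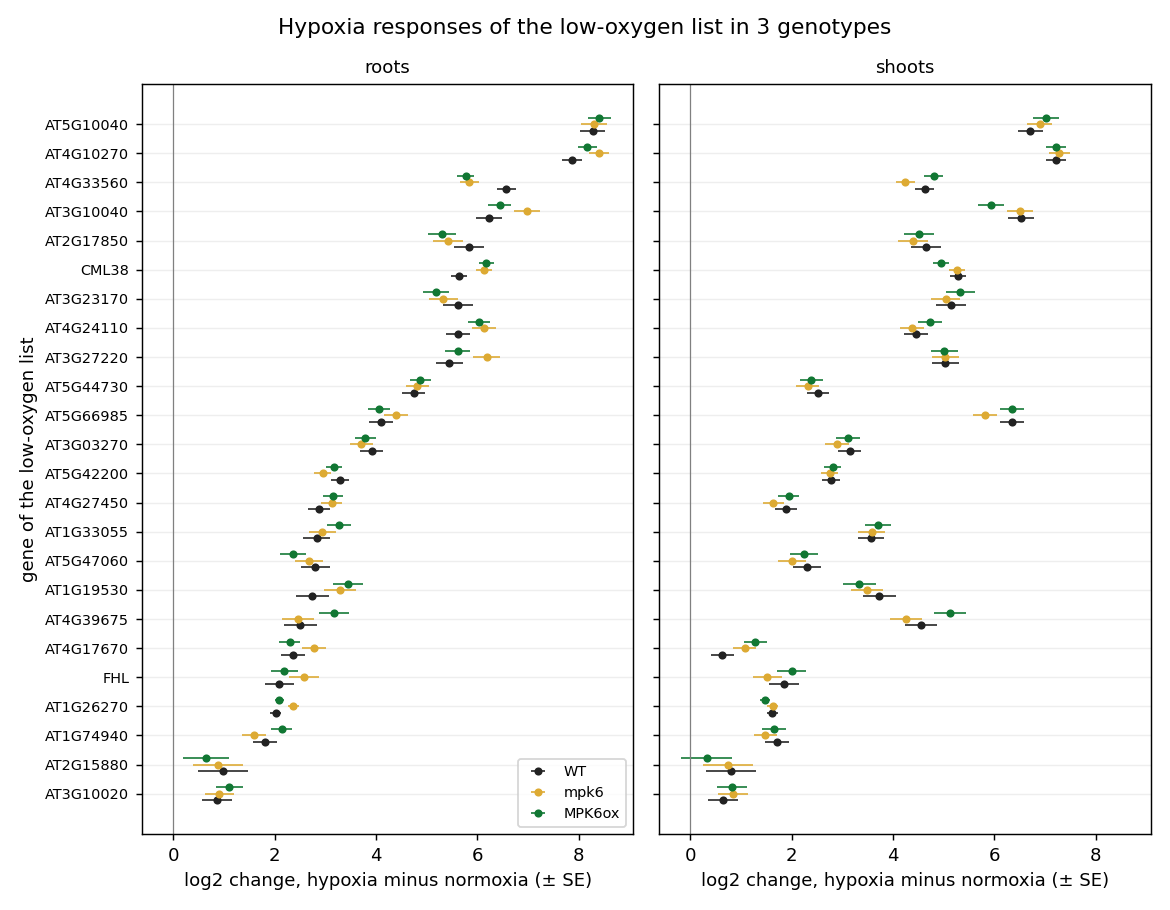
Log2 change with hypoxia (hypoxia minus normoxia, ± SE) of the 24 measured low-oxygen genes in roots and shoots, in WT (black), mpk6 (yellow) and MPK6ox (green), each point from 2 arrays against 2 (3 against 2 in MPK6ox roots). The points of the 3 genotypes lie close together along each gene, with AT5G10040 at 8.28 and AT4G10270 at 7.87 in WT roots.

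The organs shared a core response and differed around it. Of the changes in WT roots and WT shoots, 144 rises were called in both, where independent lists would share 5.47, and 30 falls, where they would share 3.91, while 2 probe sets went opposite ways. The difference between the organs was tested directly, and 153 probe sets responded differently in WT roots than in WT shoots, 81 with the higher change in roots and 72 with the lower. EXO, an exordium gene of cell expansion, rose by 1.92 in roots against -1.29 in shoots (difference 3.21 ± 0.48, adjusted p = 0.00367), and AT5G62280 rose by 1.22 in roots and fell by 1.93 in shoots (difference 3.15 ± 0.35, adjusted p = 0.000439). AT2G34400 (3.35 in roots, 0.27 in shoots), AT4G37240 (3.43 and 0.47) and AT4G30380 (4.45 and 1.20) responded more in roots. EXPA18 (-2.49 and 0.13), AT4G00910 (-2.36 and 0.03) and AT1G48690 (-2.23 and 0.05) fell in roots, and their changes in shoots did not pass. Their normoxic levels were 5.68, 5.03 and 4.42 in shoots against 10.09, 8.41 and 7.25 in roots, which left less room to fall in shoots. AT5G66985 rose more in shoots (81.3-fold) than in roots (17.1-fold), and AT2G37750 rose by 2.54 in shoots against 0.43 in roots. In normoxia both stood lower in shoots (4.61 and 8.76) than in roots (9.36 and 13.20), which left more room to rise in shoots. AT5G62280, EXO and AT4G37240 stood higher in normoxic shoots (10.06, 10.39 and 6.70) than in normoxic roots (6.30, 8.41 and 5.73). This left more room to rise in roots and to fall in shoots. For the genes with such unlike levels, response and level cannot be told apart. The largest adjusted p of the 10 was 0.0256, for EXPA18.

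Within the low-oxygen list, AT5G44730, AT4G33560 and AT4G17670 rose more in WT roots than in WT shoots by 2.23, 1.96 and 1.73, and AT5G66985 and AT4G39675 less, with differences of -2.25 and -2.04. Adjusted over the list alone, 8 rose more and 2 less in roots, and the mean difference was 0.39 (95% interval 0.05 to 0.73). By camera the changes of the low-oxygen list (adjusted p = 1.63e-05) and of fermentation (0.0429) differed between the organs. So did those of photosynthesis (5.91e-07, the higher change in roots) and abscisic acid (0.0282, the lower change in roots). Each of these calls was lost with an estimated correlation (adjusted p = 0.0745 for each). The lactate dehydrogenase gene AT4G17260 was the 1 of 4 fermentation genes with its own call (1.93, adjusted p = 0.0128), also adjusted over the list alone. The root markers EXPA7 (-1.90, adjusted p = 0.00627) and EXPA18 had the lower change in roots, and that list held with an estimated correlation (adjusted p = 0.0286). Of the 6 photosynthesis genes 0 differed over all probe sets and 6 did adjusted over the list alone. With the mean of the photosynthesis genes of the root arrays in the model, the differences of EXPA18 (from -2.62 ± 0.52, SE, to -1.83 ± 0.59, adjusted p = 0.316) and AT2G37750 (from -2.11 ± 0.41 to -1.88 ± 0.52, adjusted p = 0.178) did not pass, being smaller with wider errors. AT5G62280 is more abundant in normoxic shoots than in normoxic roots (10.06 against 6.30), and its difference passed with that mean in the model (2.66, adjusted p = 0.00554). The calls of 3 of the 10 genes depended on single arrays. AT4G30380 had an adjusted p of 0.0585 without WT root normoxia replicate 1, 0.0696 without root hypoxia replicate 1, 0.0528 and 0.0599 without shoot normoxia replicates 1 and 2, and 0.0504 and 0.0607 without shoot hypoxia replicates 1 and 2. For EXPA18 the adjusted p was 0.14 without root normoxia replicate 1, 0.132 without root hypoxia replicate 2, 0.113 and 0.094 without the shoot normoxia replicates, and 0.0997 and 0.0888 without the shoot hypoxia replicates. It was 0.078 and 0.0732 without the root normoxia replicates for AT2G37750, 0.0629 and 0.0919 without the root hypoxia ones, 0.12 and 0.0526 without the shoot normoxia ones, and 0.122 without shoot hypoxia replicate 2. The count of 153 was 87 and 96 without the root normoxia replicates, 93 without either root hypoxia replicate, 73 and 72 without the shoot normoxia replicates, and 81 and 59 without the shoot hypoxia replicates.

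Roots of mpk6 and MPK6ox responded to hypoxia much as WT roots did. AT4G10270 rose 338-fold in mpk6 (8.40) and 288-fold in MPK6ox (8.17), AT5G10040 316-fold and 340-fold, and AT3G10040 126-fold and 87.0-fold. AT3G27220, a Kelch-repeat gene, rose 73.0-fold in mpk6 roots, and CML38 72.5-fold in MPK6ox roots. Of the 731 probe sets that changed at least 2-fold in WT roots, 729 moved the same way in mpk6 roots and 730 in MPK6ox roots, with correlations across genes of 0.969 and 0.978. Genes are not independent replicates. The low-oxygen list rose by 4.18 in mpk6 roots (22 of 24 genes, 23 adjusted over the list alone; adjusted p = 7.95e-06 with an estimated correlation) and by 4.12 in MPK6ox roots (23 of 24, 23 adjusted over the list alone; 1.68e-06). PDC2 rose by 3.87 and 4.17 and AT4G17260 by 3.24 and 3.10, the list holding with an estimated correlation (adjusted p = 0.0311 and 0.00196). Among the falls, AT4G25250, a pectin methylesterase inhibitor gene, fell in both lines (-2.86 in mpk6, -2.95 in MPK6ox), the peroxidase gene AT3G49960 in mpk6 (-2.74), and AT4G37290 (-2.82) and AT5G01210 (-2.62) in MPK6ox. AT2G23270 (-3.08), AT1G34510 (-3.52) and AT3G01260 (-2.77) fell in mpk6 roots, and AT1G34510 (-3.13) and AT2G41380 (-2.60) in MPK6ox roots. Without mpk6 root hypoxia replicate 2 the adjusted p was 0.0618 for AT1G34510 and 0.0617 for AT3G01260, and without mpk6 root normoxia replicate 2 it was 0.0534 for AT3G01260. In MPK6ox roots it was 0.078 for AT1G34510 without normoxia replicate 1 and 0.0501 for AT2G41380 without normoxia replicate 2.

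In mpk6 roots 845 probe sets rose and 1433 fell, 306 and 588 of them at least 2-fold. In MPK6ox roots 973 rose and 1248 fell, 511 and 440 at least 2-fold, and 340 rises and 562 falls were called in the roots of all 3 genotypes. The mpk6 count depended on scaling, since 1815 rose and 1022 fell with arrays centred on their medians, a rising share of 64.0% against 37.1% as deposited. That centring moved the median change of all probe sets in mpk6 roots from 0.02 to 0.14. The mpk6 root hypoxia replicate 1 array had the lowest median (6.87) and the highest 3'-minus-5' signal of the control transcripts, with ubiquitin at 2.15 where the other 24 arrays ran from 1.36 to 1.68. Without that array 1148 probe sets changed in mpk6 roots, and without mpk6 root normoxia replicates 1 and 2 it was 1238 and 1046. In MPK6ox roots 1221 and 1117 changed without normoxia replicates 1 and 2.

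The other lists in mpk6 and MPK6ox roots repeated parts of the WT pattern. WRKY22 rose by 3.71 and 4.51 and WRKY53 fell by 1.36 and 1.54, the same counts adjusted over the list alone, while the MPK3 and MPK6 list did not differ from other genes by camera (adjusted p = 0.775 and 0.622). Its means were 0.74 (95% interval -0.07 to 1.54) and 0.87 (0.14 to 1.61), and its medians -0.14 and -0.35. EXPA7 fell by 2.39 and 1.98 and EXPA18 by 2.56 and 2.04, 2 of 3 root markers also adjusted over the list alone (adjusted p = 0.0311 and 0.0347 with an estimated correlation). In mpk6 roots EXPB1 (-0.68) and EXPA8 (-1.15, adjusted p = 0.0347) fell, 2 of 6 cell wall genes and 4 adjusted over the list alone, and in MPK6ox roots EXPB1 (-0.90) fell, 1 of 6 and 1 adjusted over the list alone. Both shifts of that list held with an estimated correlation (adjusted p = 0.0311 and 0.0347). CML38 carried the touch list, whose calls (camera adjusted p = 0.00423 and 0.00402) were lost with an estimated correlation (adjusted p = 0.0618 and 0.0554). LTI30, a dehydrin, fell by 0.81 in MPK6ox roots (adjusted p = 0.0108), 1 of 3 abscisic acid genes and 2 adjusted over the list alone, a list that fry called lower (adjusted p = 0.00897) and camera did not (adjusted p = 0.078).

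Photosynthesis transcripts were higher in hypoxic than in normoxic roots of WT and MPK6ox. The mean of the 6 genes went from 7.41 ± 0.06 (SD, n = 2) to 9.20 ± 0.58 (n = 2) in WT roots and from 6.85 ± 0.28 (n = 2) to 9.33 ± 0.88 (n = 3) in MPK6ox roots, against 13.2 in normoxic WT shoots. In MPK6ox roots all 6 genes rose, PSBW by 3.01, PSAN by 2.97, RCA by 2.81 and PRK by 2.33, also adjusted over the list alone. There the list held with an estimated correlation (adjusted p = 0.0347). In WT roots the list's camera call was lost with an estimated correlation (adjusted p = 0.0906). In mpk6 roots the mean went from 7.92 ± 0.70 to 8.70 ± 0.56 (n = 2 and 2), and 0 of 6 genes passed limma's threshold over all probe sets or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The difference of the response from WT was -1.01 in mpk6 roots (95% interval -2.45 to 0.42), and its camera call (adjusted p = 0.000508) was lost with an estimated correlation (adjusted p = 0.538). With the mean of these 6 genes in the model, 411 probe sets changed in MPK6ox roots, and AT1G34510 lost its call, from -3.13 ± 0.68 (SE) to 0.51 ± 0.79 (adjusted p = 0.884). AT2G41380 lost its call through a wider error, from -2.60 ± 0.52 to -3.11 ± 1.02 (adjusted p = 0.188). Since the mean of the 6 genes moved with hypoxia, these losses do not show that shoot RNA made the falls.

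**Figure D2:**
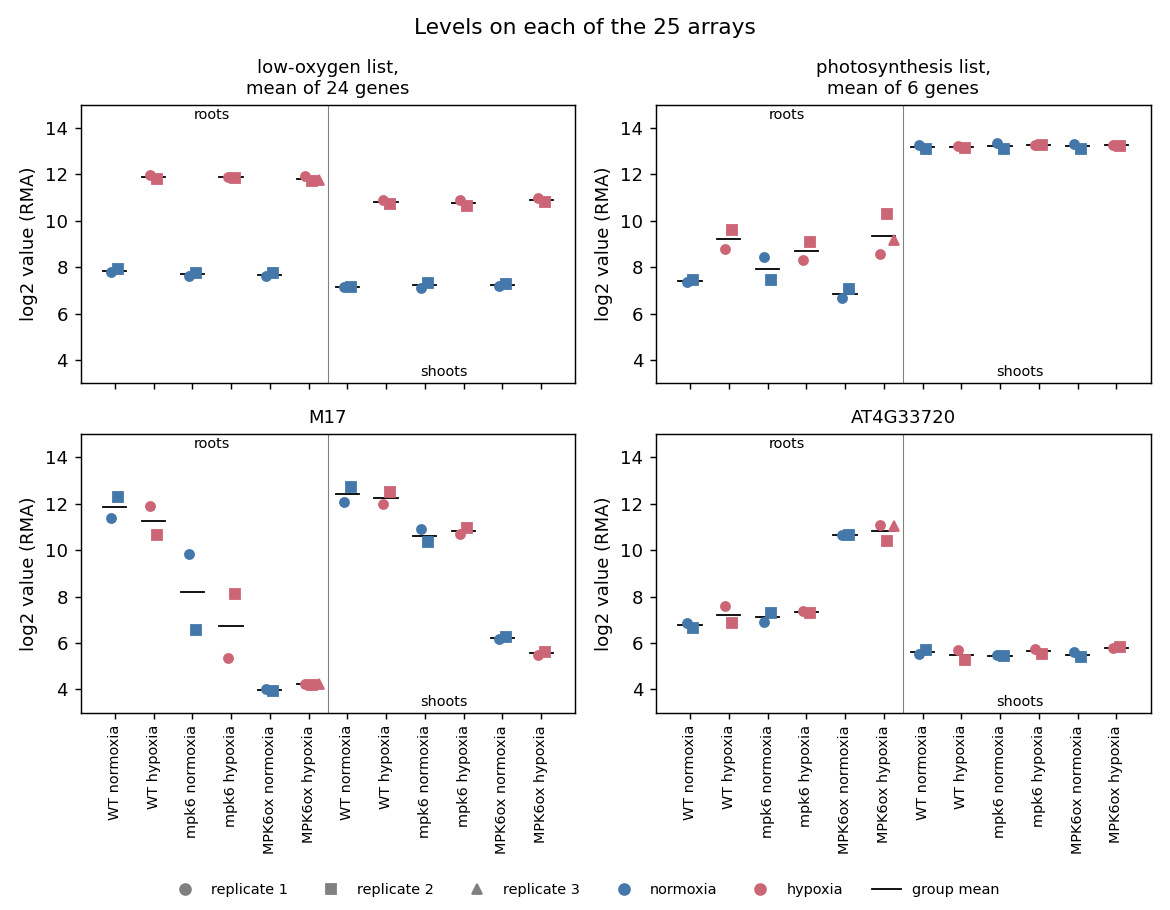
Log2 values (RMA) of each of the 25 arrays in the 12 groups, roots left and shoots right of the grey line, for the means of the low-oxygen list (24 genes) and the photosynthesis list (6 genes) and for M17 and AT4G33720; blue is normoxia, red hypoxia, symbols are replicates and black lines group means. The low-oxygen mean lies between 7.15 and 7.85 in normoxic groups and between 10.8 and 11.9 in hypoxic ones, while M17 follows genotype, from 12.4 in WT shoots to 3.96 in MPK6ox roots.

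In shoots, the genes that rose most in WT rose in mpk6 and MPK6ox too. AT4G10270 rose 156-fold and 148-fold, AT5G10040 119-fold and 130-fold, AT3G10040 90.7-fold and 60.7-fold, and AT5G66985 56.5-fold and 81.4-fold. AT5G62280 fell by 2.55 and 2.61, AT5G58900 by 2.04 and 1.93, and AT5G57760 by 1.62 in MPK6ox shoots. All 219 probe sets that changed at least 2-fold in WT shoots moved the same way in both lines. Called in the shoots of all 3 genotypes were 137 rises and 48 falls. Totals were 173 rises and 125 falls in mpk6 and 218 and 185 in MPK6ox. With the replicate block the totals of both lines were over 1.5 times as high. After centring they were 197 and 85 in mpk6, a rising share of 69.9% against 58.1%, and 239 and 124 in MPK6ox, 65.8% against 54.1%. The low-oxygen list rose by 3.54 in mpk6 shoots and 3.67 in MPK6ox shoots (22 of 24 genes in each and 23 adjusted over the list alone; adjusted p = 1.06e-07 and 1.22e-07 with an estimated correlation), and PDC2 (3.21 and 2.98) and AT4G17260 (1.12 and 1.45) rose (adjusted p = 0.0093 and 0.00641). WRKY22 rose in MPK6ox shoots (2.07, adjusted p = 0.0389) and stood at 1.91 in mpk6 shoots (adjusted p = 0.0733), 2 of 3 genes rose in each line adjusted over the list alone, and the list's camera calls (0.0167 in mpk6, 0.0214 in MPK6ox) were lost with an estimated correlation (adjusted p = 0.142 and 0.161). CML38 carried the touch list (1 and 2 of 3 genes adjusted over the list alone; adjusted p = 0.004 and 0.00454 with an estimated correlation). Heat shock genes had means of 1.12 and 1.00 with 0 of 6 past the threshold, 2 and 1 at an unadjusted p under 0.05, and 1 and 0 adjusted over the list alone, and the camera calls (0.0012 and 0.00563) were lost with an estimated correlation (adjusted p = 0.282 and 0.391). The auxin response gene IAA29 (-2.45 in mpk6, -2.43 in MPK6ox), AT1G08280 (-1.96 and -1.72) and, in mpk6, the kinase gene WAG2 (-1.83) fell, but not in every fit with an array left out. Without normoxia replicate 1 of the same line's shoots the adjusted p was 0.18 and 0.165 for IAA29 and 0.0553 and 0.113 for AT1G08280. Without normoxia replicate 2 it was 0.22 and 0.212 for IAA29, 0.0626 and 0.126 for AT1G08280 and 0.176 for WAG2. Without hypoxia replicate 1 it was 0.0777 for WAG2, and without hypoxia replicate 2 it was 0.448 and 0.364 for IAA29, 0.158 and 0.268 for AT1G08280 and 0.0587 for WAG2. IAA29 in mpk6 shoots also had 0.0509 without any 1 of the WT shoot normoxia or mpk6 root normoxia arrays, 0.0514 without either MPK6ox root normoxia array and 0.0532 without either MPK6ox shoot normoxia array. With shoots fitted alone IAA29 had 0.139 in mpk6 and 0.125 in MPK6ox, and WAG2 0.105, and with array weights IAA29 had 0.0507 in mpk6. The totals were 146 and 148 in mpk6 shoots without normoxia or hypoxia replicate 2, and in MPK6ox shoots 174 and 156 without the normoxia replicates and 156 without hypoxia replicate 2.

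Whether MPK6 alters the response to hypoxia, the question of the series, was tested as the difference of the hypoxia effects between each line and WT. In limma 0 probe sets passed in mpk6 roots, mpk6 shoots, MPK6ox roots and MPK6ox shoots, with 853, 409, 515 and 244 at an unadjusted p under 0.05. With the replicate numbers as a block 0 passed as well, with 1448, 716, 1387 and 377 at an unadjusted p under 0.05. Evenly spread p-values would give 1137, but same-numbered arrays deviated together, so the lower unblocked counts are no measure of how alike the genotypes were. Without the block the smallest adjusted p were 0.997, 1, 0.459 and 1, and the median 95% interval of a single probe set was ± 0.54 log2, or ± 0.51 in MPK6ox roots. For the low-oxygen list the mean differences from WT were 0.13 in mpk6 roots (95% interval -0.21 to 0.47), -0.11 in mpk6 shoots (-0.45 to 0.23), 0.08 in MPK6ox roots (-0.25 to 0.40) and 0.01 in MPK6ox shoots (-0.33 to 0.36). For fermentation they were -0.07 (-0.44 to 0.30), -0.04 (-0.41 to 0.33), 0.22 (-0.14 to 0.58) and -0.05 (-0.42 to 0.32), and 0 members of either list passed over all probe sets or adjusted over the list alone. The MPK3 and MPK6 list differed from WT by -0.22 in mpk6 roots (-1.36 to 0.92). Photosynthesis was the only list that camera called, at -1.01 in mpk6 roots (adjusted p = 0.538 with an estimated correlation) and 0.69 in MPK6ox roots, where the call (adjusted p = 0.0369) was lost with an estimated correlation (adjusted p = 0.78). The counts of 0 became 47 in mpk6 roots without mpk6 root hypoxia replicate 2, 1 in mpk6 shoots without WT shoot hypoxia replicate 2 or mpk6 shoot hypoxia replicate 2, and 1 in MPK6ox shoots without WT shoot hypoxia replicate 2.

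What the loss of MPK6 changes apart from hypoxia was tested within each organ and treatment. AT5G04120, a phosphoglycerate mutase-like gene, was 5.14-fold higher in mpk6 than in WT roots in normoxia (10.88 against 8.52, difference 2.36 ± 0.29, n = 2 and 2, adjusted p = 0.00468), and AT3G29410, of the terpene synthase family, 4.24-fold higher (2.08 ± 0.26, adjusted p = 0.00468). In hypoxic roots AT3G29410 was 5.04-fold higher (adjusted p = 0.0018) and AT5G04120 3.45-fold (adjusted p = 0.0375), while AT2G28780 was lower (-1.73, adjusted p = 0.00204). AT2G16005, of the MD-2-related lipid-binding family, was 5.26-fold higher in normoxic mpk6 shoots (10.08 against 7.69, adjusted p = 0.00114) and 4.76-fold in hypoxic ones (adjusted p = 0.00269). The totals were 12 higher and 4 lower in normoxic roots, 4 and 7 in hypoxic roots, 2 and 0 in normoxic shoots and 1 and 0 in hypoxic shoots. With the replicate numbers as a block they were 29 and 14 in normoxic roots and 24 and 48 in hypoxic roots. With roots and shoots fitted separately they were 0 and 0 in roots of either treatment, 1 in normoxic shoots and 0 in hypoxic shoots, and every gene named here lost its call, with adjusted p from 0.0862 for AT2G16005 in normoxic shoots to 0.411 for AT1G65570 (0.173 for AT5G04120 and AT3G29410 in normoxic roots). In hypoxic roots centring gave 4 and 4, a higher share of 50.0%. Without WT root normoxia replicate 2, AT5G04120 (adjusted p = 0.0845) and AT3G29410 (0.07) lost their normoxic calls. Without mpk6 root hypoxia replicate 1, AT3G29410 (0.0564), AT5G04120 (0.495) and AT2G28780 (0.0778) lost their hypoxic ones, and AT2G28780 also without WT root hypoxia replicate 2 (0.0637). AT5G04120 in hypoxic roots lost its call also without WT root hypoxia replicate 1 (0.18) or 2 (0.202), MPK6ox root hypoxia replicate 3 (0.0545), either WT shoot normoxia array (0.0613), either WT shoot hypoxia array (0.0636), either mpk6 shoot normoxia array (0.0609), either MPK6ox shoot normoxia array (0.0551) or either MPK6ox shoot hypoxia array (0.0617). AT2G16005 lost its normoxic call without WT shoot normoxia replicate 1 (0.0702) and its hypoxic call without WT shoot hypoxia replicate 1 (0.156) or mpk6 shoot hypoxia replicate 2 (0.0751). XTH33, a cell wall transglucosylase gene, was higher in normoxic roots (1.06, adjusted p = 0.021), a call lost without WT root normoxia replicate 2 (0.324) or mpk6 root normoxia replicate 1 (0.102) or 2 (0.0588). AT1G21010 (-1.35, adjusted p = 0.0342) and the sugar kinase family gene AT3G59480 (-1.04, adjusted p = 0.0353) were lower in hypoxic roots. Without WT root hypoxia replicate 2 these had 0.0722 and 0.202, without mpk6 root hypoxia replicate 1 0.495 each, without either WT shoot hypoxia array 0.0598 and 0.0636, and AT1G21010 had 0.251 without WT root hypoxia replicate 1 and AT3G59480 0.0617 without either MPK6ox shoot hypoxia array. AT1G65570 (1.52) and AT5G51470 (1.03) in normoxic roots and AT2G39040 (0.85) in hypoxic roots had adjusted p between 0.0375 and 0.0477, and each lost its call without any 1 of 13 or more arrays. In hypoxic roots calls were also lost with array weights, which left the changes as they were with wider errors, and with the photosynthesis mean as a covariate, where they were 1.69, 0.82, -1.36 and -1.05, by AT5G04120 (adjusted p = 0.142 and 0.091), AT2G39040 (0.123 and 0.0844), AT1G21010 (0.123 and 0.0647) and AT3G59480 (0.142 and 0.0647), and in normoxic roots by AT5G51470 with quantile normalization (0.0645) and the covariate (0.0584).

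These small mpk6 counts moved with single arrays. In normoxic roots the 16 became 28 and 0 without WT root normoxia replicates 1 and 2, 36 and 4 without mpk6 root normoxia replicates 1 and 2, and 26 without MPK6ox root hypoxia replicate 2. It was 9 without any 1 of the WT shoot normoxia, WT root hypoxia, WT shoot hypoxia or MPK6ox shoot hypoxia arrays, and 10 without any 1 of the mpk6 shoot normoxia or MPK6ox shoot normoxia arrays. In hypoxic roots the 11 became 0 without mpk6 root hypoxia replicate 1 and 944 without replicate 2, the 566 higher and 378 lower then resting on the single array with the high 3'-minus-5' signal. It became 4 and 1 without WT root hypoxia replicates 1 and 2, 22 without either WT root normoxia array, 7 without any 1 of the WT shoot normoxia or MPK6ox root normoxia arrays or MPK6ox root hypoxia replicate 3, 5 without either mpk6 shoot normoxia array, 4 without either MPK6ox shoot hypoxia array and 3 without either WT shoot hypoxia array. In normoxic shoots the 2 became 0 and 1 without WT shoot normoxia replicates 1 and 2, 13 without mpk6 shoot normoxia replicate 1, and 4 without any 1 of the WT root arrays. In hypoxic shoots the 1 became 0 and 2 without WT shoot hypoxia replicates 1 and 2 and 2 without either MPK6ox shoot hypoxia array.

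Over both organs and both treatments, where 8 arrays of mpk6 stood against 8 of WT, 36 probe sets were higher and 48 lower in mpk6. Whole seedlings were dissected, so same-numbered root and shoot arrays may come from the same plants. The fit counted them as separate samples, so its p-values may be too small. AT2G16005 was 2.73-fold higher (1.45 ± 0.13, adjusted p = 7.29e-05), AT5G04120 2.72-fold (1.44 ± 0.15, adjusted p = 0.000293) and AT1G14960, of a latex-protein-like family, 1.04 higher. M17, a late embryogenesis abundant gene, was 7.22-fold lower (-2.85 ± 0.41, adjusted p = 0.00454), with the defensin genes LCR67 (-2.54) and PDF2.1 (-2.07), the thionin gene AT2G15010 (-2.13, adjusted p = 0.00104) and PAP85, a vicilin-like seed storage gene (-1.62, adjusted p = 0.00412). With the replicate numbers as a block, 87 were higher and 118 lower, 205 in total. Of the lists, salicylic acid and pathogen defence was called lower (camera adjusted p = 0.0472, mean -0.28) with 0 of 3 members past the threshold, also adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.281). The low-oxygen list stood at -0.04 (95% interval -0.16 to 0.08). AT5G23840 (0.96, adjusted p = 0.0269) and AT1G66800 (0.95, 0.0314) lost their calls without any 1 of 9 and 12 arrays, with adjusted p of up to 0.0807 and 0.0853. The 84 became 131 and 40 without WT root normoxia replicates 1 and 2, 37 without WT shoot normoxia replicate 2, 50 without WT root hypoxia replicate 1, and 52 and 49 without WT shoot hypoxia replicates 1 and 2. It became 38 without mpk6 root normoxia replicate 2, 37 without mpk6 shoot normoxia replicate 2, 40 without mpk6 root hypoxia replicate 1, and 53 and 55 without mpk6 shoot hypoxia replicates 1 and 2.

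MPK6ox differed from WT in more probe sets than mpk6 did, above all in transcripts that were far lower. M17 stood at 11.86 ± 0.64 in normoxic WT roots and at 3.96 ± 0.07 in MPK6ox roots (SD, n = 2 and 2), a difference of -7.89 ± 0.82 (SE, adjusted p = 0.000129). The difference was -7.06 in hypoxic roots, -6.18 in normoxic shoots and -6.69 in hypoxic shoots, and no fold is given for MPK6ox, since its root levels lie near the bottom of the range of array values. The beta-glucosidase gene BGLU19 differed by -5.33, -5.21, -5.34 and -5.66 in the same 4 comparisons, and the cupin gene AT2G28490 and the AWPM-19-like gene AT1G04560 were among the 5 lowest in each. AT3G02480, of a late embryogenesis abundant family, was lower in normoxic roots (-4.01) and AT3G54940, a papain-type protease gene, in normoxic shoots (-4.46). Among transcripts that were higher, AT4G33720, of the CAP family that holds PR-1, was 14.8-fold up in normoxic roots (10.65 ± 0.02 against 6.76 ± 0.16, difference 3.89 ± 0.23, adjusted p = 2.58e-07) and 12.3-fold in hypoxic roots, and AT3G08820, a pentatricopeptide repeat gene, 6.34-fold and 5.77-fold. In shoots, the cytochrome P450 gene CYP71B22 was 9.30-fold higher in normoxia and 7.03-fold in hypoxia, the peroxidase gene Prx37 8.52-fold in normoxia (3.09) and by 2.65 in hypoxia, and the subtilase gene SBT3.3 6.48-fold in normoxia (2.70). OSM34, an osmotin-like gene, was higher by 2.80 and 2.58, and CCOAMT, a lignin methyltransferase gene, by 2.70 in normoxic shoots. Whether the MPK6ox difference itself differed between the organs was not tested.

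The totals for MPK6ox against WT were 21 higher and 54 lower in normoxic roots, 38 and 50 in hypoxic roots, 94 and 108 in normoxic shoots and 33 and 79 in hypoxic shoots, and 2 higher and 33 lower probe sets were called in all 4 comparisons. With roots and shoots fitted separately 29 and 24 were called in normoxic and hypoxic roots, and calls were lost by AT3G24510 (adjusted p = 0.0543), AT1G51920 (0.175) and AT1G04560 (0.0701) in normoxic roots, AT1G26380 (0.237), AT4G26120 (0.12), AT2G28490 (0.0508) and AT1G04560 (0.116) in hypoxic roots, and SBT3.3 (0.104) and AT4G16260 (0.0655) in hypoxic shoots. Without WT root hypoxia replicate 1, calls in hypoxic roots were lost by AT1G26380 (main difference 2.68, adjusted p = 0.803), AT3G29970 (0.118), AT4G26120 (0.346), AT2G28490 (0.0805) and AT1G04560 (0.168). AT1G26380 lost it also without MPK6ox root hypoxia replicate 1, 2 or 3 (adjusted p = 0.0938, 0.0709 and 0.067). In normoxic roots AT1G51920 (1.92) lost its call without WT replicate 1 (0.0939) and MPK6ox replicates 1 and 2 (0.0558 and 0.138). In normoxic shoots the adjusted p was 0.137 for OSM34 and 0.309 for CCOAMT without WT replicate 1, 0.141 for CCOAMT without WT replicate 2, 0.0541 and 0.22 for the same genes without MPK6ox replicate 1, and 0.0923 and 0.262 without MPK6ox replicate 2. In hypoxic shoots it was 0.283 for OSM34 and 0.0639 for AT4G16260 without WT replicate 1, 0.0732 for OSM34, 0.0705 for SBT3.3 and 0.0732 for AT4G16260 without WT replicate 2, and 0.05 for Prx37, 0.283 for OSM34 and 0.137 for AT4G16260 without MPK6ox replicate 2. The totals became, in normoxic roots, 31 without WT replicate 2 and 28 and 31 without MPK6ox replicates 1 and 2, and, in hypoxic roots, 13 without WT replicate 1 and 54 and 47 without MPK6ox replicates 1 and 3. In normoxic shoots they became 103 without WT replicate 2 and 98 and 105 without MPK6ox replicates 1 and 2, and in hypoxic shoots 74 and 46 without WT replicates 1 and 2 and 42 without MPK6ox replicate 2.

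Over both organs and both treatments, with 9 MPK6ox and 8 WT arrays, 321 probe sets were higher and 201 lower in MPK6ox, 57 and 95 of them at least 2-fold. As for mpk6, root and shoot arrays that may share plants were counted as separate samples. Lower transcripts included M17 (-6.96 ± 0.40, adjusted p = 2.97e-08), BGLU19 (-5.39), AT2G28490 (-5.08) and AT1G04560 (-4.57). These are differences of array values, and since background was not assessed, the fall in transcript that they stand for was not measured. AT1G26380 and AT1G26420, which encode berberine-bridge-like oxidases, were higher by 2.24 ± 0.27 and 1.63 ± 0.34 (adjusted p = 7.11e-05 and 0.011), CCOAMT by 2.02 and OSM34 by 1.82. With the replicate numbers as a block 521 were higher and 271 lower, 792 in total. No list was called, the low-oxygen list stood at -0.02 (95% interval -0.14 to 0.10), and LTI30 was the only list member of the 11 tested lists to pass (-0.67, adjusted p = 0.000754), also adjusted over the list alone. The averaged mpk6 and MPK6ox comparisons, which use the same WT arrays, shared 38 lower and 5 higher probe sets. Independent lists would share 0.424 and 0.508. In 20 simulations every array, WT included, was simulated as unchanged, and at most 0 lower ones were shared. Unchanged groups give few calls to share, so this count does not show what sharing WT arrays adds to the overlap. The correlation of the fold changes across genes was 0.461, against 0.510 in the simulations, and the covariance 0.0171 against 0.00628. With the WT arrays split so that each line had its own controls, the correlation was 0.392 or 0.190, the covariance 0.0151 or 0.00882, and 28 or 14 lower probe sets were shared. Same-numbered WT root and shoot arrays, which may share plants, went to different lines in these splits.

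The remaining lists fixed beforehand showed few or no calls. The mitochondrial dysfunction list had 0 of 9 genes past limma's threshold in each of the 6 hypoxia comparisons, with 1 at an unadjusted p under 0.05 in each but MPK6ox shoots, where it was 0. NDB2 (-0.89) in WT roots was its only gene to pass adjusted over the list alone, and camera did not call the list. The abscisic acid list had 0 of 3 past in WT roots, with 2 at an unadjusted p under 0.05 that also passed, lower, adjusted over the list alone, and fry called it lower (adjusted p = 0.0287) where camera did not (adjusted p = 0.116). WRKY53 was the 1 of 3 salicylic acid genes that fell in WT, mpk6 and MPK6ox roots, and GRX480 (1.09) rose in WT roots adjusted over the list alone. Lists with a single measured gene had 0 calls over all probe sets in any comparison: in WT roots and shoots STZ of the peroxide list stood at 0.29 and 1.53, EIN3 of the ethylene list at -0.15 and -0.26, AMY1 of the starvation list at 0.06 and -0.09, AUR1 of the cell division list at 0.25 and 0.00, and the clock gene GI at -0.74 and -0.36. In the 6 hypoxia comparisons only STZ, in the shoots of WT, mpk6 and MPK6ox, had an unadjusted p under 0.05, and it passed there adjusted over the list alone. The median, mean and camera direction differed in sign in 23 of 143 list tests, of which camera had called only the touch list in WT roots.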

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

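The tests of shoot RNA, with the photosynthesis mean as a covariate, of the authors' normalization, of seeds, of a graded MPK6 effect and of splits that part all pairs were chosen only after the results were seen, and the tests of linked chromosome stretches and of other splits were set beforehand.

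The response to hypoxia differed between WT roots and WT shoots in 153 probe sets, by a test of the difference itself. The named differences, root minus shoot, were 3.25 for AT4G30380, 3.21 for EXO, 3.15 for AT5G62280, 3.08 for AT2G34400, 2.96 for AT4G37240, -2.62 for EXPA18, -2.40 for AT4G00910, -2.28 for AT1G48690, -2.25 for AT5G66985 and -2.11 for AT2G37750. The organs differ by design. EXPA18, AT4G00910, AT1G48690, AT5G66985 and AT2G37750 also had lower normoxic levels in shoots, and AT5G62280, EXO and AT4G37240 higher ones. For all of these response and level cannot be told apart. At normoxic shoot levels, the 4.85% of shoot RNA fitted to hypoxic WT roots would raise AT5G62280 by 0.68 of its 1.22 in roots. It would raise EXO by 0.19 of its 1.92 and move each of the other 8 by between -0.07 and 0.07. In hypoxic shoots AT5G62280 changed by -1.93 and EXO by -1.29 (not called), so hypoxic shoot RNA would raise them less. The contributions at hypoxic shoot levels were not computed. With the photosynthesis mean as a covariate 8 of the 10 differences passed, AT5G62280 at 2.66 and EXO at 4.03. EXPA18 (-1.83) and AT2G37750 (-1.88) did not. That mean rose with hypoxia in WT roots, so the covariate also takes up part of the response.

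Photosynthesis transcripts were higher in hypoxic than in normoxic roots of WT and MPK6ox, with 0 of 6 genes called in mpk6 roots. The contrast with mpk6 was not called with an estimated correlation. The list's camera call in WT roots was also lost with an estimated correlation (adjusted p = 0.0906). The probe sets nearest in level to these 6 genes did not move with them. Their median change was -0.07 in WT roots (1200 probe sets, 95% interval -0.09 to -0.05) and -0.0125 in MPK6ox roots (783, -0.04 to 0.02). The mean rises of the 6 genes were 1.79 and 2.48. Since the arrays are alike in distribution, as after a quantile-type normalization, such medians lie near 0 anyway. They thus cannot exclude the authors' normalization as a cause. Although roots and shoots were dissected apart, shoot tissue or shoot RNA in the hypoxic root samples may account for the rise: over 1211 shoot-enriched probe sets, the changes predicted from an added share of shoot RNA had slopes of 0.821 in WT and 0.842 in MPK6ox (0.895 in mpk6), with r across genes of 0.699, 0.795 and 0.382. The fitted shares were 4.85% in WT, 6.15% in MPK6ox and 1.54% in mpk6, and 1027, 1078 and 884 of these probe sets had higher values in hypoxia. Predicted and observed changes share the normoxic root means, and the probe sets were chosen partly for low normoxic WT root values. Noise in those means can thus give a positive slope by itself. The slope was also highest in mpk6, which had the smallest share. A response of root cells to hypoxia in these genes stays open as untested.

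Seed maturation and storage transcripts were lower in MPK6ox and mpk6 than in WT: in a list of 37 measured genes made after the result was seen, 24 were lower in MPK6ox (mean -1.65, 95% interval -1.91 to -1.40) and 9 in mpk6, averaged over organs and treatments. In mpk6 the mean was -0.63 (95% interval -0.90 to -0.37), and in its hypoxic shoots alone -0.23 (-0.76 to 0.30). Within each organ and treatment 0 of the 37 were called lower in mpk6. For MPK6ox it was 17 and 12 in normoxic and hypoxic roots and 22 and 19 in normoxic and hypoxic shoots. Since the list was made after the fall was seen in these arrays, its intervals are no separate test of the fall. With separate WT arrays for each line, the 28 members not called lower in both lines had means of -0.38 (-0.62 to -0.14) and -0.46 (-0.71 to -0.22) in mpk6 in the 2 splits of the WT arrays. In MPK6ox these means were -1.30 and -1.22. The splits gave same-numbered WT root and shoot arrays, which may share plants, to different lines. An effect graded with the amount of MPK6 would not by itself put both lines below WT, but this test cannot decide on it. The amount of MPK6 was not measured, and seeds in the WT samples could put both lines lower whatever MPK6 does. Seeds or seed coats left in the WT and mpk6 samples may account for the pattern, since the amounts above the MPK6ox level correlated across 24 genes between WT roots and WT shoots at 0.987, and at 0.874 to 0.974 between other groups. Because these genes were chosen as lower in MPK6ox and share its baseline, draws of 24 from the 72 other genes called lower in MPK6ox were set beside them, and these reached a median of 0.846, with a share of 7e-04 at least as high. The draws were not matched in level or range, and a wider range raises r by itself, so they do not show one source. Across the 24 genes the log2 ratio of these amounts had an SD of 0.372 between WT roots and WT shoots. It was 0.458 and 0.593 between mpk6 shoots and WT shoots and roots, and 0.932 to 0.986 in pairs with mpk6 roots. A seed programme shared by both organs would give the same proportions, so the correlation does not part it from seeds. An effect of either line on it stays open as untested.

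The probe sets that differed between each line and WT over both organs and treatments were set against other splits and against gene order. For mpk6, 1 of 100 splits within organ and treatment, the real one, gave as many as its 84, the highest other giving 20, and for MPK6ox 2 of 100 gave as many as its 522, the highest other, near the real split with 2 of 17 arrays exchanged, giving 575. Few of these splits part the same-numbered pairs as the real one does, 14 for mpk6 and 11 for MPK6ox, the real one included. Among 100 splits that part all 8 pairs, 1 gave as many for mpk6, the real one, with the highest other at 9. For MPK6ox it was 1 too, with the highest other, 1 pair exchanged, at 236. With the replicate block 1 of 100 gave as many as 205 (the highest other 28) and 1 as many as 792 (the highest other 307). The splits exchange root and shoot arrays separately, although these may come from the same seedlings, so chance differences between the plants cannot be excluded. For linked stretches of chromosome, 262 called genes of MPK6ox and 45 of mpk6 were placed in gene order. A pair of neighbours was 2 called genes within 10 measured genes of each other. Random draws gave at least as many pairs of called neighbours in a share of 0.283 for MPK6ox (51 pairs against a median of 47) and 0.784 for mpk6 (1 pair). Called genes thus did not lie this close together more often than in random draws. Linked stretches with calls spaced wider, or among the other called probe sets, would be missed and cannot be excluded. Besides these and chance differences between the plants, an effect of the genotypes, and any difference between the seed stocks, stays open as untested.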

How the results depend on the processing

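The settings with shoot-enriched probe sets left out, with the photosynthesis mean as a covariate and with seed genes left out were chosen only after the results were seen, and the cause of the differences was not tested. No total moved by over 1.5 times with centring or with quantile normalization, which says little about stability since the deposited values were already alike in distribution, but rises in mpk6 roots alone went from 845 to 1815 with centring. With the replicate block, counts were 2579 in WT root hypoxia, 617 in WT shoot, 3686 in mpk6 root, 620 in mpk6 shoot and 888 in MPK6ox shoot, 43 and 72 for mpk6 against WT in normoxic and hypoxic roots, 268 for the organ difference, 205 for mpk6 and 792 for MPK6ox averaged. The block ended 1 camera call, photosynthesis in MPK6ox roots against WT (0.0571), and no call of a named gene. In the same organ 24 of 24 arrays correlated better with their own replicate number, a hint from the data, not the design. A component with 36.4% of the within-group variance had 12 of 12 replicate 1 arrays below 0 and 12 of 12 replicate 2 arrays above. Its sign was set to put the mean of replicate 1 below 0. In groups of 2 arrays the deviations mirror each other, so the results of replicates 1 and 2 are not separate. Fitted separately, roots gave 852 for WT hypoxia, 0 and 0 for mpk6 against WT in normoxia and hypoxia, and 29 and 24 for MPK6ox against WT, and shoots 1 and 0 for mpk6 against WT. Array weights gave 526 in WT shoot hypoxia, 1361 in mpk6 root, 231 for the organ difference, and 3 and 4 for mpk6 against WT in hypoxic roots and normoxic shoots. Trend and robust settings gave 19 and 4 there, and without dim probe sets the first was 17. The covariate gave 521 in WT root hypoxia, 411 in MPK6ox root, and 28 and 3 for mpk6 against WT in normoxic and hypoxic roots, and it turned AT1G34510 in MPK6ox roots from -3.13 to 0.51, the only reversed value. The covariate itself rose with hypoxia in WT and MPK6ox roots, so it also takes up part of the hypoxia effect. Without shoot-enriched probe sets root hypoxia counts were 1355, 2314 and 1923 in WT, mpk6 and MPK6ox.

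With each array left out in turn, where a lone remaining sample is assumed to vary like the other groups, counts ran from 612 to 1632 in WT root hypoxia, 127 to 326 in WT shoot, 1046 to 3277 in mpk6 root, 146 to 325 in mpk6 shoot, 1117 to 2321 in MPK6ox root and 156 to 432 in MPK6ox shoot. For mpk6 against WT they ran from 0 to 36 and 0 to 944 in normoxic and hypoxic roots, and 0 to 13 and 0 to 2 in shoots. For MPK6ox against WT they ran from 28 to 84, 13 to 98, 98 to 211 and 42 to 119 in the same order. Differences of the hypoxia effect ran from 0 to 47 in mpk6 roots, 0 to 1 in mpk6 shoots, 0 to 0 in MPK6ox roots and 0 to 1 in MPK6ox shoots, 59 to 201 between organs, and the averaged comparisons 37 to 131 for mpk6 and 399 to 556 for MPK6ox. Of the 163 named-gene values all kept their direction and call with the block, centring, no dim probe sets or trend and robust settings, 162 with quantile normalization, 158 with array weights and 150 with the covariate, and 99 of 133 did with separate organs. Leave-one-out kept 3867 of 4075. Of 143 list tests an estimated correlation ended 18 calls, fry ended 9 and added 3, and centring ended 1, while all 6 rises of the low-oxygen list held under each. Signal near background was not assessed beyond leaving out the dimmest 5687 probe sets.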

Other observations

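All tests in this part were chosen after the results were seen. Beyond the low-oxygen list, a wider set of genes followed hypoxia in both organs: 103 probe sets rose and 17 fell in all 6 hypoxia comparisons. Among the 54 named genes that rose in all 6, the following were chosen after their values were seen: TIL, a lipocalin gene of stress tolerance, GID1A, a gibberellin receptor gene, PUB22, an E3 ubiquitin ligase gene, and AT3G29970, of the B12D family. Families grouped by symbol were tested with camera in 8 comparisons (31 families of at least 8 measured genes). Of these 248 tests 24 were called, in 14 families, and 0 of the 24 held with an estimated correlation, so those named here are a choice among them. Expansin genes (EXPA) were lower after hypoxia in roots, with 3 of 10 falling in WT, 5 in mpk6 and 3 in MPK6ox (adjusted p = 0.000716, 0.00105 and 0.00141), and glycosyltransferase genes (UGT) with 9 of 47 falling in WT roots and 10 in MPK6ox roots (adjusted p = 0.00227 and 0.000468). None of the calls of EXPA and UGT held with an estimated correlation (adjusted p = 0.132, 0.151 and 0.127 for EXPA, 0.251 and 0.127 for UGT). In mpk6 roots 10 UGT genes fell and 2 rose, and the family was not called (adjusted p = 0.0983). Genes of the plastid genome were higher after hypoxia in MPK6ox roots, where 16 of 69 rose (adjusted p = 7.44e-15, lost with an estimated correlation, adjusted p = 0.252). They were also called higher in WT roots and MPK6ox shoots, with 1 of 69 rising in each (adjusted p = 0.000763 and 0.000366, lost with an estimated correlation, adjusted p = 0.794 and 0.676), and the photosynthesis list had a mean change of 0.05 in MPK6ox shoots. They were not called in mpk6 roots, where 0 of 69 rose and camera's direction was down (adjusted p = 0.564), or in WT and mpk6 shoots (adjusted p = 0.131 and 0.462).

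In MPK6ox, averaged over organs and treatments, called genes, named after their values were seen, included neighbours of the same family: AT1G26380, AT1G26410 and AT1G26420, of the berberine-bridge-like oxidases, were higher by 2.24, 1.37 and 1.63, and CYP71B22, CYP71B23, CYP71B24 and CYP71B36, of the cytochromes P450, by 1.62, 0.84, 1.39 and 0.38. The family of CYP genes was higher in this comparison with 5 of 26 called (adjusted p = 0.00837), which was lost with an estimated correlation (adjusted p = 0.17), and so was the UGT family, with 2 of 47 higher and 1 lower (adjusted p = 0.0155, lost at 0.374).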
